A study of Mus musculus with 3 samples.

How the data were processed

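Single-cell RNA sequencing libraries were made from otic vesicles of E10.5 mouse embryos, with 1 library from the Sox9 Y440X heterozygote (group CD in the labels) and 2 wild-type libraries (WT replicates 1 and 2). Per the labels' protocols, the libraries were made with the 3.1 version of the droplet-based Chromium 3' kit, in which each captured transcript carries a unique molecular identifier (UMI). Per the submitters' processing notes, reads were processed with Cell Ranger 6.0 and build mm39, and the file header gives version 6.0.0. The deposited matrices hold whole-number UMI counts per gene and barcode over 32285 features, with no normalisation by the authors. No coordinates are given here.

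Barcodes with at least 1000 detected genes and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet in scanpy 1.11.5 (expected rate 5%, run per library with its automatic threshold) were removed. The calls took 3.42% of CD replicate 1, 2.80% of WT replicate 1 and 3.85% of WT replicate 2. After this, 8256, 6380 and 10594 cells remained, with median depths of 18319, 20054 and 15282.5 UMIs. Counts were log-normalised, 2000 variable genes were chosen with the library as batch (haemoglobins, Xist and Y-linked genes left out), and 30 principal components with 15 nearest neighbours gave 28 Leiden clusters (leidenalg 0.10.2, resolution 1) without integration of the libraries. Clusters were named from marker lists fixed before the data were examined. The scoring thresholds for naming were set after the clusters had been seen. A mean marker score of at least 1.2 (log2) and at least 3 raised markers were required, and no other class could have more markers among the leading genes. A cluster whose cells had a median under 33.3% of the median UMI count of their own library stayed unnamed if none of its markers led it or if at least 70% of its cells came from 1 library. These thresholds left 2 clusters unnamed, with 0.872% of the cells of CD replicate 1, 1.72% of WT replicate 1 and 5.30% of WT replicate 2.

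Counts were summed per library and class, since cells are not replicates, and classes with at least 50 cells in each library were tested. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. This design has 1 residual degree of freedom, which comes from the WT pair alone, and the lone CD library was assumed to vary like WT. The test also borrows spread across genes, with a median prior of 8.04 degrees of freedom in otic epithelium and 209 in endothelium. A p-value therefore rests only in part on the WT spread of its own gene. SE values are the log2 fold change divided by the square root of the F statistic. Levels are CPM, the UMI count of a gene scaled to the TMM-adjusted total of its library and class. Nothing in the labels says that the WT pools are separate litters, so p-values measure the spread between these samples, which may be technical. A chi-square comparison of the WT libraries gave 109 per degree of freedom over 19543 genes, so they are not the same counts deposited again. The smallest p that a permutation of 1 against 2 libraries can give is 0.333, so no permutation test was run.

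Gene lists fixed before the data were examined (26 lists, 4 lists of otic domain markers and 14 lists of cell type markers), together with mitochondrial and ribosomal protein genes, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The plan names this test for otic epithelium, and its use in the other classes goes beyond the plan. The difference of the genotype effect between classes was tested as an interaction with the library as a block. Otic epithelium-like cells were clustered again with the same settings, and a sub-cluster was named for an otic domain where at least 2 of its 10 leading genes, more than for any other domain, and at least 3 raised genes were markers of that domain. Domains and sub-clusters with at least 50 cells per library were tested like the classes. Shares of cells with a UMI were compared after thinning each cell to 5000 UMIs, leaving out shallower cells. Intervals on shares are exact (Clopper-Pearson) at 95% and cover counting error only.

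The named genes follow a rule set before the data were examined. It takes Sox9, Sox10, Sox8 and Sox2 in the 4 main classes and 15 genes of otic domains. It also takes the genes past the threshold with the largest changes (up to 10 each way in otic epithelium and 5 in other classes) that have a mean of at least 10 CPM and a change against each WT library exceeding the gap between the WT libraries. From each list named it takes up to 4 members past the threshold, or the 2 of smallest p as values. In a class with 0 genes past the threshold it takes the 5 of smallest p each way, as values only. Predicted genes and mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes were passed over when the largest changes were chosen. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

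The test was tried on simulated counts with 200 changed genes per class. The simulation gave every gene the common dispersion of its class, and the CD library the same dispersion as WT. Only genes with a WT mean of at least 10 CPM were changed. Real genes differ in spread, so the recovered numbers and false calls need not hold for the real counts. In otic epithelium, 65 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered, with 10 false calls among 16517 genes tested. The recovered numbers were 54 and 100 in mesenchyme (14924 genes, 7 false calls), 64 and 100 in neuroblasts and neurons (13976 genes, 4 false calls), and 30 and 91 in neural crest and glia (11467 genes, 4 false calls). Alternatives tried were RLE size factors, DESeq2 1.42.0, no gene filter, equal cells and UMIs per library, doublets kept, looser and stricter cell filters, a batch-balanced graph, Leiden resolution 2, otic cells without the sub-clusters led by cell cycle or neuroblast genes, and each WT library left out. A sub-cluster counted as led with at least 3 such genes among its 10 leading ones. A single sub-cluster met that limit, for cell cycle genes. Further alternatives were added after the data had been seen, and the closing section names them.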

Results

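The data are UMI counts from 3 libraries of pooled, dissociated otic vesicles, the epithelial sacs that form the inner ear, taken from mouse embryos at E10.5. The library labelled CD carries 1 copy of Sox9 with the Y440X change, a premature stop in the transcription factor SOX9. It held 186439890 UMIs over 12322 barcodes. WT replicate 1 held 157373393 UMIs over 8330 barcodes and WT replicate 2 held 202584468 over 16649. The study asks how SOX9 and Wnt activity oppose each other in the otocyst and how SOX10 controls the endolymphatic part of the ear. With a single CD library, a difference between the genotypes cannot be told apart from a difference between that pool and the others.

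The Sox9 transcript level was higher in the CD library than in both WT libraries in each of the 4 main classes, without passing the threshold over all genes in any of them. In otic epithelium-like cells it stood at 696 CPM in CD replicate 1, 440 CPM in WT replicate 1 and 370 CPM in WT replicate 2 (log2 fold change 0.78, SE 0.15, edgeR adjusted p = 0.140). In mesenchyme-like cells the levels were 346, 251 and 243 CPM, in neuroblasts and neurons 91.1, 66.6 and 54.8 CPM, and in neural crest and glia 49.1, 41.4 and 45.5 CPM. A Sox9 UMI was found in 89.5% of CD otic cells thinned to 5000 UMIs, against 79.4% and 73.6% in the WT libraries, and the unthinned shares were 94.5%, 94.1% and 87.6%. In mesenchyme-like cells, many of which express Sox9 themselves, the thinned shares were 73.3%, 62.7% and 59.6% and the unthinned ones 87.6%, 83.9% and 80.5%. A 3' tag does not read the changed codon and counts both alleles together, so these values do not check the genotype.

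Otic epithelium-like cells made up a similar share of each library. They were 44.0% of CD replicate 1 (95% interval 42.9 to 45.0), 45.2% of WT replicate 1 and 45.5% of WT replicate 2, a WT mean of 45.3% ± 0.237 (SD, n = 2). Neuroblasts and neurons made up 12.4% of CD cells, against 11.9% and 10.7%. Mesenchyme-like cells made up 26.2%, against 20.02% and 28.8%, and the neural crest and glia class 2.14%, against 3.997% and 1.94%. Neural tube progenitor-like cells ranged from 0.774% in WT replicate 2 to 7.37% in WT replicate 1, with CD at 5.10%. These shares can follow from the dissection, and no test was run on them.

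**Figure D1:**
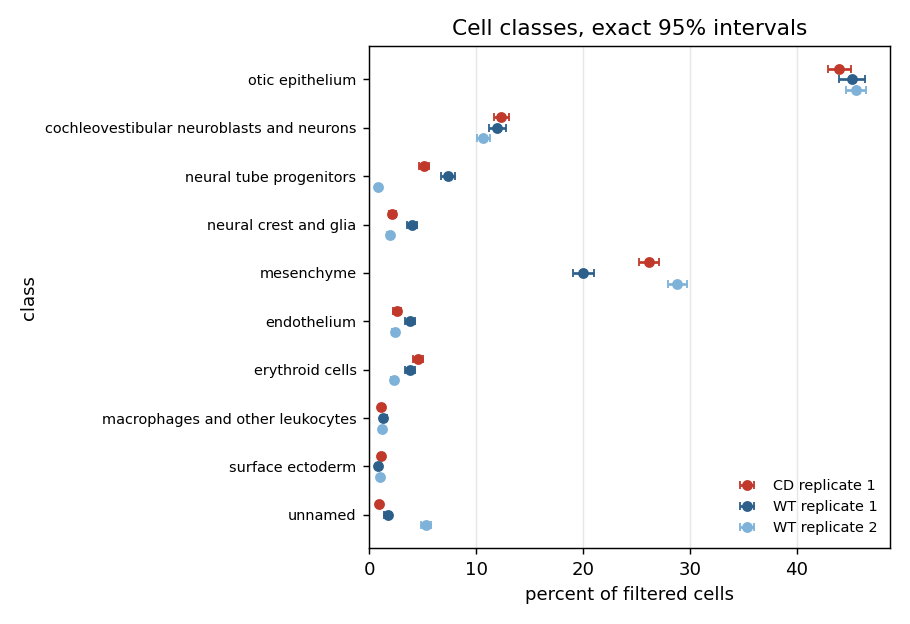
Share of filtered cells in each marker-named class (percent, x axis) for the 3 libraries, with exact 95% binomial intervals that cover counting error only. The otic share lies between 44.0% and 45.5% in all 3 libraries, while neural tube progenitors range from 0.774% to 7.37%.

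In otic epithelium-like cells, Oc90 and Otol1, which encode proteins of the otolith matrix, and the cartilage gene Cnmd fell in the CD library. Oc90, which encodes the main matrix protein of otoconia, was at 81.2 CPM in CD and 818 ± 375 CPM in WT (SD, n = 2; log2 fold change -3.33, SE 0.37, edgeR adjusted p = 0.0152). Cnmd, the cartilage matrix glycoprotein chondromodulin, fell from 104 ± 6.85 CPM to 15.6 CPM (log2 fold change -2.74, SE 0.17, edgeR adjusted p = 0.000982). Otol1, the otolith collagen otolin, fell with a log2 fold change of -1.13 (SE 0.15).

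Of 16823 genes tested by edgeR in this class, 5 rose and 14 fell at an adjusted p of 0.05. Others that fell were Fxyd3, a regulator of the sodium pump (-2.47, SE 0.22), Bricd5 (-2.16, SE 0.22), Sphk1, a sphingosine kinase (-1.32, SE 0.18), and the Wnt ligand Wnt7b (-1.22, SE 0.17). Runx1t1, a transcriptional corepressor, rose from 16.9 ± 0.544 to 39.5 CPM (log2 fold change 1.23, SE 0.15). Nrp2, a receptor for semaphorins and VEGF, rose from 60.8 ± 4.04 to 128 CPM (1.08, SE 0.14). The other genes that rose were Gad2, a GABA-synthesising enzyme (7.64 CPM in CD, 1.10 and 0.987 CPM in WT), Cbln2 and Grm4, which lie outside the rule and were chosen after their values were seen. At an unadjusted p under 0.05 there were 794 genes, where uniform p-values would give 841. DESeq2 called 80 genes, all 19 among them, while the looser cell filter called 7, without, among others, Oc90, Otol1, Sphk1, Wnt7b, Runx1t1 and Nrp2. Sphk1 and Wnt7b also lost the call without low-UMI cells.

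**Figure D2:**
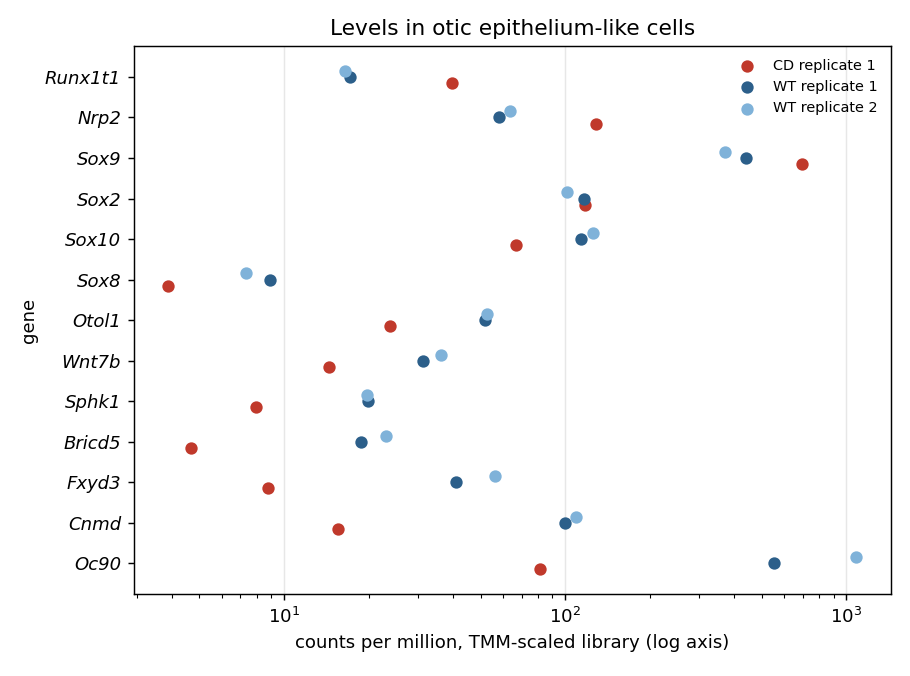
Levels of the named genes in otic epithelium-like cells, in CPM on a log axis, with 1 point per library. Oc90 sits at 81.2 CPM in CD and at 552 and 1083 CPM in the WT libraries, and Sox9 at 696 CPM in CD against 440 and 370 CPM.

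Sox10 and Sox8, the closest relatives of Sox9, did not pass the threshold over all genes. Sox10 stood at 67.0 CPM in CD and 120 ± 8.85 CPM in WT (log2 fold change -0.84, SE 0.15, edgeR adjusted p = 0.123). Sox8 stood at 3.87 CPM against 8.12 ± 1.10 CPM (-1.07, SE 0.23), and Sox2, a prosensory factor, at 117 against 109 ± 10.7 CPM (0.10, SE 0.15). Of 14 SOX genes measured, 0 passed over all genes by edgeR, and adjusted over the list alone 1 rose (Sox9) and 2 fell (Sox10 and Sox8). Sox9 and Sox10 each passed over all genes in 6 of 12 alternatives, DESeq2 among them. A Sox10 UMI was found in 27.8% of CD otic cells thinned to 5000 UMIs, against 41.6% and 44.0% in WT, and in 1.14%, 1.51% and 2.89% of mesenchyme-like cells, which should lack it. The unthinned shares were 59.0%, 82.8% and 73.0% in otic and 4.26%, 5.56% and 9.30% in mesenchyme-like cells, and thinning left out 357, 139 and 521 otic and 227, 154 and 354 mesenchyme-like cells. Median depths before thinning were 19540, 22602 and 16383 UMIs in otic cells and 19310, 20469 and 17183 in mesenchyme-like cells.

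Of 46 lists tested in otic epithelium, 6 passed upward and 8 downward by camera, and 0 with an estimated correlation. With an estimated correlation the test has 1 residual degree of freedom, so a list could hardly pass in any class. Its smallest unadjusted p by camera in otic epithelium was 0.106. The adjusted p-values with an estimated correlation therefore decide for no list, and the preset correlation is an assumption. The list of cartilage and SOX9-bound matrix genes was shifted downward in otic epithelium (17 measured, median log2 fold change -0.41, adjusted p = 5.74e-17). Of its members 0 rose and 1 fell over all genes, and adjusted over the list alone 1 rose and 4 fell. The collagen genes Col9a3 (47.0 CPM in CD, 96.8 and 127 CPM in WT) and Col9a1 (65.8 CPM against 113 and 133 CPM) had log2 fold changes of -1.25 and -0.91. Hapln1, a link protein of cartilage, was the member that rose adjusted over the list alone (0.83, SE 0.20). These 3 genes lie outside the rule in this class and were chosen after their values were seen. The list's adjusted p = 0.891 with an estimated correlation. The SOX10-dependent glial and crest genes were shifted downward too (13 measured, median -0.33, adjusted p = 9.41e-08, and adjusted p = 0.891 with an estimated correlation). Adjusted over the list alone 1 member rose and 4 fell. Markers of neural crest and glia (median -0.33, adjusted p = 9.41e-08), chondrogenic mesenchyme (median -0.24, adjusted p = 1.66e-07) and endothelium (median -0.47, adjusted p = 0.0123) were shifted downward, as were otic epithelium markers (3 of 37 fell, median -0.04, adjusted p = 2.79e-08). Erythroid markers were shifted upward (median 0.46, adjusted p = 2.57e-07), and for each of these lists the adjusted p = 0.891 with an estimated correlation.

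Wnt/beta-catenin targets were shifted upward by camera, with 15 of 18 measured members positive (median 0.32, adjusted p = 5.11e-06, and adjusted p = 0.891 with an estimated correlation). By edgeR 0 of them passed over all genes, and adjusted over the list alone 2 rose. These were Notum, a secreted Wnt deacylase (19.0 CPM against 9.67 ± 1.78, log2 fold change 0.98), and Lef1, a transcription factor of the pathway (60.7 against 42.4 ± 1.09 CPM, 0.52). Axin2, a feedback target, had a log2 fold change of 0.45 (SE 0.16, edgeR adjusted p = 0.804). Of 18 Wnt ligands measured 1 fell over all genes, Wnt7b, and the list did not pass (camera adjusted p = 0.859). The Wnt antagonist Sfrp1 stood at 146 CPM in CD and 292 ± 17.0 CPM in WT (edgeR adjusted p = 0.0617), and it passed in 7 of 12 alternatives.

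BMP pathway genes were shifted upward (19 measured, median 0.25, camera adjusted p = 1.48e-04, and adjusted p = 0.891 with an estimated correlation), with 0 past the threshold over all genes and 3 that rose adjusted over the list alone. They were the ligand Bmp4 (66.6 CPM in CD, 36.3 and 42.2 in WT) and the homeobox genes Msx2 and Msx1, the last chosen after its value was seen. FGF pathway genes were also shifted upward (median 0.07, adjusted p = 0.0365, and adjusted p = 0.891 with an estimated correlation), and genes of the unfolded protein response downward (median -0.15, adjusted p = 0.00686, and adjusted p = 0.891 with an estimated correlation). Neurogenesis genes (adjusted p = 0.652), the Notch pathway (0.668), prosensory genes (0.218) and hedgehog targets (0.565) did not pass. All 7 haemoglobins were higher in the CD library in this class (median 0.83, camera adjusted p = 4.89e-19), 12 of 13 mitochondrial genes were positive (median 0.26, adjusted p = 1.19e-04) and 2 of 81 ribosomal protein genes were (median -0.17, adjusted p = 5.25e-12). For these 3 lists, too, the adjusted p = 0.891 with an estimated correlation.

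**Figure D3:**
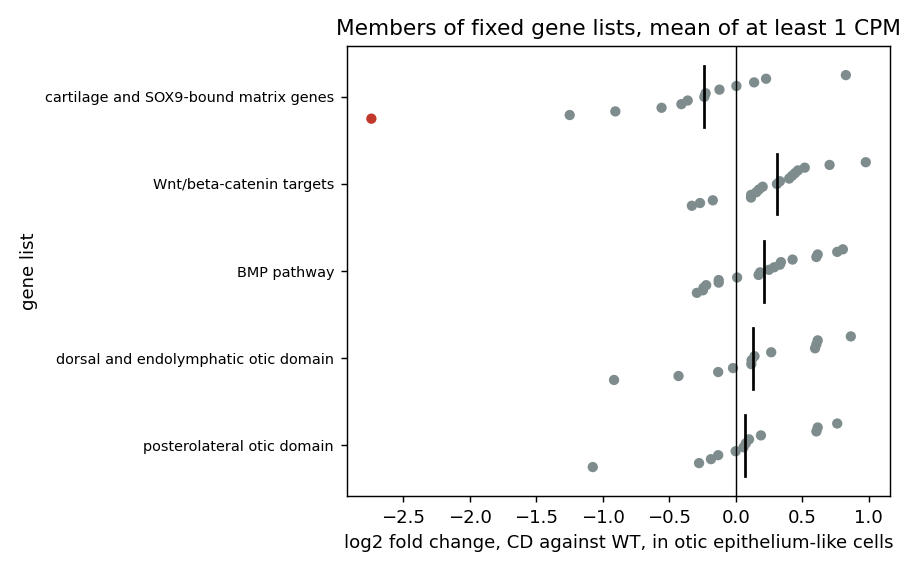
Log2 fold changes, CD against WT, of the members of 5 fixed lists with a mean of at least 1 CPM in otic epithelium-like cells, with 1 point per gene and a black bar at the median. Wnt/beta-catenin targets lie mostly above 0, and Cnmd at -2.74 is the red point, past an edgeR adjusted p of 0.05.

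Genes of the dorsal, endolymphatic part of the otocyst went both ways. Wnt2b, a dorsal Wnt ligand, stood at 4.73 CPM in CD and 2.59 ± 0.364 CPM in WT (log2 fold change 0.86, SE 0.23, edgeR adjusted p = 0.363), and Gbx2, a dorsal homeobox gene, at 51.2 against 33.9 ± 6.29 CPM (0.60). Dlx5 (0.14), Dlx6 (0.12) and Lmx1a (0.12) had small changes. Slc26a4, the endolymphatic anion exchanger, and Foxi1, its regulator, were under 1 CPM in all 3 libraries. Slc26a4 stood at 0.107 CPM in CD and 0.601 and 0.703 CPM in WT (log2 fold change -2.60, SE 0.57, edgeR adjusted p = 0.209), and it passed in 1 of 12 alternatives, without a gene filter (adjusted p = 0.00210). Of 15 measured members of the dorsal list 0 passed over all genes by edgeR, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.265). In the posterolateral list, Otx2 stood at 22.4 CPM in CD and 47.2 ± 6.28 CPM in WT (-1.08, SE 0.17, edgeR adjusted p = 0.0737). Tbx1 (-0.19), Pax2 (-0.20), Lfng (0.05) and Neurog1 (0.24) did not pass.

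Otic cells were clustered again into 17 sub-clusters. By the naming rule 4 sub-clusters were posterolateral, but in 1 of them cell cycle genes outnumbered posterolateral markers among the 10 leading genes (3 against 2), so its name does not hold. In the pool of all 4, 1 of 14100 genes passed by edgeR, Cnmd, which fell. Otx2 fell less there than in the whole class (log2 fold change -0.51, edgeR adjusted p = 0.9997). The sub-clusters with Otx2 as first leading gene held 6.53% and 2.07% of CD otic cells. Their shares were 11.7% and 3.02% in WT replicate 1 and 7.65% and 4.25% in WT replicate 2. Whether the mix of cells makes part of the Otx2 difference was not tested. In the sub-cluster led by ventral prosensory and neurogenic markers 4 of 11210 genes passed, among them Runx1t1, which rose, and Oc90 and Ss18l2, which fell, the last outside the rule and chosen after its value was seen. Tested singly, a test that the plan did not hold, the other 3 posterolateral sub-clusters gave 81, 53 and 39 genes past the threshold, the one with more cell cycle genes gave 19, and the 17 sub-clusters ranged from 4 to 175. No sub-cluster met the naming rule for the dorsal or the medial markers. The unnamed sub-clusters with Dapl1, Rdh10 and Snx7 as first leading gene had the most raised dorsal markers (9, 8 and 8). Of their 10 leading genes 0, 0 and 1 were dorsal markers. Tested singly they gave 75, 175 and 164 genes past the threshold. The Snx7 sub-cluster held 6.12% of CD otic cells, against 3.61% and 2.59% in WT. The CD share lay below both WT libraries in the Dapl1 sub-cluster and between them in the Rdh10 sub-cluster. The plan compares domain sizes only where the genes that define them do not differ. That was not shown here, so the shares above are values only. With the called and named genes left out of the clustering, Oc90, Cnmd, Fxyd3, Col9a1, Col9a3 and Sox10 lay below both WT libraries in 17 of 17 sub-clusters tested, and Sox9 and Runx1t1 above both in 17 of 17. Nrp2 lay above both in 15 of 17. Otx2 was tested in 12 of these sub-clusters, with a lower value in 11, a higher one in 1, and below both WT libraries in 10. The sub-cluster with Nrp2 as its first leading gene held 7.05% of CD otic cells, against 5.31% and 5.81% in WT. Whether the mix of cells makes part of the Nrp2 rise was not tested. All these sub-clusters come from the same 3 libraries and are not replicates.

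**Figure D4:**
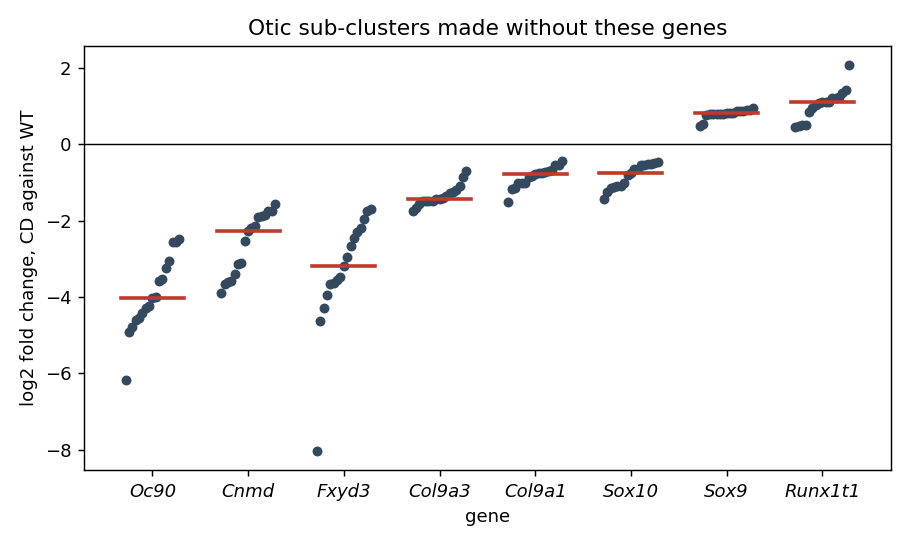
Log2 fold change, CD against WT, in each of 17 otic sub-clusters made without these genes, with 1 point per sub-cluster and a red bar at the median. The medians are -4.03 for Oc90, -2.26 for Cnmd and 0.81 for Sox9, and the lowest point, for Fxyd3, is a fitted value from 0 CD counts.

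In cochleovestibular neuroblasts and neurons, the cells that will form the hearing and balance nerve, 5 genes rose and 5 fell among 14296 tested by edgeR, with 297 at an unadjusted p under 0.05, where uniform p-values would give 715. Xaf1, an interferon-inducible pro-apoptotic gene, rose from 14.9 ± 1.15 to 43.4 CPM (SD, n = 2; log2 fold change 1.54, SE 0.20, adjusted p = 0.00124), and Dqx1 rose from 81.5 ± 12.5 to 166 CPM (1.03, SE 0.19). The neuropeptide gene Sst fell from 92.0 ± 15.7 to 32.8 CPM (-1.49, SE 0.21), and Col9a3 fell from 14.9 ± 0.597 to 4.98 CPM (-1.58, SE 0.27). Oc90 fell here too (2.92 CPM against 33.5 and 47.7). Sox10 (-1.22), Sox9 (0.59), Sox2 (0.08) and Sox8 (-0.27) did not pass. Notch pathway genes (median 0.08, camera adjusted p = 0.0173) and ventral otic domain genes (15 of 16 positive, median 0.17, adjusted p = 1.47e-04) were shifted upward, with adjusted p = 0.782 and adjusted p = 0.742 with an estimated correlation, and 0 members passed by edgeR over all genes. Among the former Hes1 stood at 96.6 CPM in CD and 73.4 ± 9.01 in WT. DESeq2 called 5 genes, all among these 10. Sst, Col9a3 and Dqx1 lost the call without a gene filter, Sst and Col9a3 with equal cells and UMIs, Col9a3 with DESeq2, and Sst, Col9a3 and Oc90 with the looser cell filter.

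In mesenchyme-like cells, Oc90 was the single gene past the threshold of 15233 tested by edgeR (2.42 CPM in CD, 14.8 and 45.5 CPM in WT, log2 fold change -3.65), and DESeq2 called 0. At an unadjusted p under 0.05 there were 227 genes, and Oc90 passed in 6 of 12 alternatives (log2 fold change -2.39 without WT replicate 2). Sox9 stood at 346 CPM against 247 ± 5.59 CPM (0.49, SE 0.16). The cartilage list was shifted downward by camera (15 measured, median -0.42, adjusted p = 3.91e-11), with 0 past the threshold over all genes and 3 that fell adjusted over the list alone. Hedgehog targets (10 of 12 positive, adjusted p = 4.20e-04) and Wnt antagonists (8 of 12 positive, adjusted p = 9.98e-04) were shifted upward. For all 3 lists the adjusted p = 0.724 with an estimated correlation. Otic epithelium markers were shifted downward in this class as well (median -0.62, adjusted p = 9.56e-18, and adjusted p = 0.724 with an estimated correlation). Of the cartilage list, Cnmd and Col9a3 stood in WT mesenchyme at 2.498% and 13.7% of their WT otic levels, and Col9a1 at 120%. Whether free otic RNA makes part of the shift of the cartilage list was not tested.

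In neural crest and glia, 0 of 11731 genes passed by edgeR and 0 by DESeq2, with 170 at an unadjusted p under 0.05. Sox10, the factor that defines this lineage, was level at 301 CPM in CD and 292 ± 0.394 CPM in WT (0.04, SE 0.21). Neurogenesis genes were shifted upward (13 of 17 positive, median 0.68, camera adjusted p = 6.60e-06, and adjusted p = 0.851 with an estimated correlation), and adjusted over the list alone 2 rose. Neurod1, a neuronal differentiation factor, stood at 20.4 CPM against 9.43 ± 0.343 CPM (1.11, but -0.28 with the looser cell filter), and Insm1 at 8.79 against 2.88 ± 0.583 CPM (1.59).

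Among the smaller classes, 6 genes rose and 18 fell in endothelium-like cells (11598 tested by edgeR), and 4 rose and 2 fell in neural tube progenitors (12364 tested). In endothelium the chemokine gene Cxcl12 (4.42 CPM in CD, 22.6 and 10.7 CPM in WT, log2 fold change -1.92), Unc5b (-1.30) and Gja4, a gap junction gene of arteries (-0.89), fell. The neuronal gene Tubb3 (-1.63) and Crabp1 (-1.49), a member of the retinoic acid list, fell too. Of 7 haemoglobins 5 fell in endothelium (median -1.43, camera adjusted p = 5.72e-05, and adjusted p = 0.810 with an estimated correlation), where in otic epithelium all 7 were higher. In neural tube progenitors the hindbrain segment gene Hoxb1 rose (28.7 CPM in CD, 0.432 and 1.03 CPM in WT, log2 fold change 5.72, SE 0.59), and Isl1, a motor neuron gene, rose too (2.30, SE 0.45). Hoxb1 lost the call with equal cells and UMIs and with the genes left out of the clustering, and Isl1 passed in 3 of 10 alternatives (0.95 with the looser filter). With a WT library left out, and 0.5 CPM added before the log2, the Hoxb1 log2 difference was 4.25 to 4.97. WT replicate 2 gave 82 cells to that class, and DESeq2 called 1 gene in it. In endothelium DESeq2 and the looser cell filter each called 0 genes, with 421 at an unadjusted p under 0.05 by edgeR, and these 5 named genes also lost the call with equal cells and UMIs and with doublets kept. Cxcl12 had a log2 fold change of -1.18 without WT replicate 1, -1.10 with the stricter filter and -0.87 with doublets kept, and Unc5b -0.38 with equal cells and UMIs. Tubb3 (0.46) and Crabp1 (0.38) turned positive with the stricter filter, and Crabp1 (0.18) with doublets kept. In erythroid cells, macrophages and other leukocytes, and surface ectoderm 0 genes passed by edgeR, with 173, 184 and 288 at an unadjusted p under 0.05, and DESeq2 called 0, 4 and 0.

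The difference of the CD effect between otic epithelium and mesenchyme was tested as an interaction. Of 17223 genes 0 passed by edgeR, with 539 at an unadjusted p under 0.05, and 17 passed without a gene filter, the interaction not having been run with another tool. Nrp2 (log2 fold change 1.08 in otic epithelium, 0.07 in mesenchyme, difference 1.00, SE 0.11) came closest among the named genes, with an adjusted p = 0.0809, and Runx1t1 differed by 0.90 (adjusted p = 0.225). The log2 fold changes in otic epithelium and mesenchyme were -2.74 and -2.79 for Cnmd, -3.33 and -3.65 for Oc90, and -2.47 and -2.48 for Fxyd3. Cnmd and Fxyd3 stood at 2.61 and 1.97 CPM in WT mesenchyme, and 0 of these 2 passed there. The Cnmd level was 2.498% of its otic level, where the median of 25 otic markers in blood and endothelial cells was 1.51% and 4.72% in the WT libraries, so a change within mesenchymal cells is not shown.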

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

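Of the tests below, the interaction between classes, the refit with equal cells and UMIs and the comparison of Oc90 with other otic markers in blood and endothelial cells were set beforehand, while the share of the change kept in that refit and all other tests were chosen only after the result was seen.

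The CD effect differed between otic epithelium and the neuroblasts and neurons for 196 of 17000 genes by an edgeR interaction test, with 104 more positive and 92 more negative in otic epithelium. Of the named genes, Runx1t1 (otic minus neuronal log2 effect 1.03, adjusted p = 1.24e-23) and Nrp2 (1.17, adjusted p = 1.31e-27) had log2 effects of 1.23 and 1.08 in otic epithelium and 0.21 and -0.09 in neurons. The differences were -1.74 for Fxyd3 (adjusted p = 1.53e-10), -1.15 for Xaf1 (adjusted p = 5.17e-07) and -0.59 for Dqx1 (adjusted p = 8.64e-04), and the last 2 rose in neurons. For Otx2 (1.55), Dlx5 (0.93) and Lmx1a (0.69) the level in the neurons of the CD library was 0.595, 3.63 and 5.30 CPM, against 3.03 to 4.34, 5.07 to 7.51 and 7.80 to 7.90 CPM in WT. The test has 1 residual degree of freedom and rests on 1 CD library. In neurons alone, setting WT replicate 1 or WT replicate 2 apart gave 50 and 142 genes, against 10 for the real split. Whether a structure between the WT libraries adds to the 196 genes was not tested.

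Oc90 fell in the CD library in otic epithelium, neurons, neural tube progenitors, mesenchyme and endothelium, and its values were lower in neural crest and glia, erythroid cells and surface ectoderm. In pooled erythroid, endothelial and leukocyte cells Oc90 stood at the fraction of its otic level that the median of 25 other otic markers had, with a largest log2 departure of 0.281 over the 3 libraries, so free RNA from otic cells may carry the difference into other classes. Free RNA does not account for the difference within otic epithelium, since after subtraction of the mesenchyme level the CD library was still 6.85-fold below the nearer WT library. CD lay below both WT libraries in 17 of 17 sub-clusters made without Oc90. Less free Oc90 RNA could lower every sub-cluster too, and it was not taken off there. A smaller number of Oc90-rich cells is therefore not excluded. The genotype and a difference between the pools, such as the exact stage, also stay open, and neither was tested.

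In otic epithelium Cnmd, Col9a1, Col9a3 and Sox10 were lower and Sox9 was higher in the CD library. Another mix of otic cells is argued against by the sub-clusters made without these genes, since each of the 5 genes lay outside both WT libraries in 17 of 17 tested. Free RNA was not taken off in these sub-clusters, which limits that argument. With equal cells and UMIs per library, the least stable of them kept 86.5% of its log2 change, which argues against depth. Mesenchymal RNA is argued against for Cnmd, Col9a3 and Sox10, whose WT mesenchyme level was at most 13.7% of the otic level, and for Col9a1 the needed 39.1% of mesenchymal RNA compares with 2.94%, the median of 26 mesenchyme markers. A candidate explanation is the genotype, as a hypothesis, with strain, stage and pool of the single CD library open.

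The 19 genes past the threshold in otic epithelium compare with 11 for the split that sets WT replicate 1 apart and 1 for WT replicate 2. The real split is the 1 of 3 with as many, and 3 splits are too few for a share under 0.05. In neuroblasts and neurons the real split gave 10 genes and the others 50 and 142, in mesenchyme 1 against 121 and 119, and in neural crest and glia 0 against 83 and 177. In these 3 classes the splits that part the WT libraries call many times the real count, which points to a structure between the WT libraries. In otic epithelium the split that sets WT replicate 2 apart also gave more genes at an unadjusted p under 0.05 than the real split, 1441 against 794, although 1 passed the adjustment.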

How the results depend on the processing

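Of the alternatives, 4 were chosen after the data had been seen: the called and named genes left out of the clustering, cells under a low UMI limit left out, the unnamed low-UMI cluster counted as mesenchyme, and sub-clusters made without those genes. No paired analysis was possible because the groups share only replicate number 1. Scrublet did not work in WT replicate 2 under the looser cell filter (0.0131% called), so that setting keeps its doublets. Over 125 named gene values and 1699 comparisons with alternatives, 1491 kept direction and side of the threshold, 77 lost the call, 71 gained one and 8 changed sign, and 52 values from leaving out a WT library moved by more than the WT spread. Cnmd, Fxyd3 and Bricd5 passed under all 12 alternatives with a test in otic epithelium, and Runx1t1, Nrp2, Oc90 and Otol1 under 11.

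The count of genes in otic epithelium (19) was 80 with DESeq2, 266 without a gene filter (more low genes tested), 84 with equal cells and UMIs, 7 with the looser and 134 with the stricter cell filter, 32 at Leiden resolution 2, 98 without the sub-cluster led by cell cycle genes and 79 with the genes left out of the clustering. That sub-cluster had 3 cell cycle genes among its 10 leading genes and held 582 cells. No sub-cluster met the limit for neuroblast genes. Sub-clusters with Mki67 or Top2a further down their leading genes stayed in. In neuroblasts and neurons (10) the count was 5 with DESeq2, 4 without a gene filter, 52 with doublets kept, 4 with the looser and 47 with the stricter filter, 19 with the balanced graph, 48 at resolution 2 and 49 without low-UMI cells. Equal cells and UMIs also gave 10 genes there, of which 4 were among the main 10. In neural crest and glia (0) the count was 8 without a gene filter and 1 each with equal cells and UMIs, doublets kept and the balanced graph. In mesenchyme (1) it was 0 with DESeq2, the looser and stricter filters, the balanced graph, resolution 2 and the added cluster, 6 with equal cells and UMIs and 2 with doublets kept. In the other classes (30) it was 5 with DESeq2, 128 without a gene filter, 56 with equal cells and UMIs, 10 with the looser and 62 with the stricter filter, 53 with the balanced graph and 13 without low-UMI cells. The values for the stricter filter and without low-UMI cells are sums over 4 classes instead of 5, since surface ectoderm was not tested there. The interaction of otic epithelium with mesenchyme (0) gave 17 genes without a gene filter, 4 with the balanced graph, 5 with the genes left out and 9 without low-UMI cells. The number of gene lists past the threshold in otic epithelium (14) was 0 with an estimated correlation, where a list could hardly pass. The otic share, CD minus the WT mean (-1.38 percentage points), was 1.75 with the looser and -3.48 with the stricter filter, -1.74 at resolution 2 and -1.14 with the genes left out. The cause of these changes was not tested.

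The sign changed for Neurog1 in otic epithelium (-0.037), Sox8 (0.72) and Sox2 (-0.039) in neurons with equal cells and UMIs, for Sox8 in neurons (0.24) and for Tubb3 (0.46) and Crabp1 (0.38) in endothelium with the stricter filter, for Crabp1 in endothelium with doublets kept (0.18), and for Neurod1 in neural crest and glia with the looser filter (-0.28). The Sox9 log2 difference in otic epithelium was 0.66 to 0.91 when a WT library was left out, which leaves no test.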

Other observations

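The lists were fixed before the data were examined, but the plan names their test for otic epithelium alone, so the list tests here go beyond it. The HOX genes, which mark position along the body axis, were shifted upward in the CD library in mesenchyme (5 of 5 positive, median log2 fold change 0.62, camera adjusted p = 3.19e-06, and adjusted p = 0.724 with an estimated correlation). They were also shifted upward in neural crest and glia (5 of 5 positive, median 0.80, adjusted p = 1.39e-08, and adjusted p = 0.851 with an estimated correlation). By edgeR 0 of them passed over all genes in either class. Hoxa3 stood at 25.9 CPM in the neural crest and glia of CD and at 12.97 and 4.26 CPM in WT, and Hoxa2 at 47.1 CPM in the mesenchyme of CD and at 26.5 and 36.6 CPM in WT. In neural crest and glia, genes of hypoxia and glycolysis were shifted downward (1 of 19 positive, median -0.22, adjusted p = 2.51e-04, and adjusted p = 0.851 with an estimated correlation).

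In macrophages and other leukocytes, Lyz2, the lysozyme of myeloid cells, stood at 284 CPM in CD and 975 ± 80.8 CPM in WT (SD, n = 2; edgeR adjusted p = 0.566), and Cd14, a receptor for bacterial lipopolysaccharide, at 50.3 against 10.9 ± 1.33 CPM. The class held 93, 85 and 129 cells.

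The 2 unnamed clusters held mostly cells of 1 library each. Of the 626 cells of the larger, low-UMI cluster 551 came from WT replicate 2, and of the 117 cells of the smaller 90 came from WT replicate 1.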
